A study of Mus musculus with 8 samples.

How the data were processed

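The samples were 4 KLF13 ChSP libraries and 4 input libraries from HT22 cells. Per the labels' protocols, cells with BirA were transfected with a plasmid for biotin-tagged KLF13, crosslinked, and their chromatin sonicated and precipitated on streptavidin. The labels number the libraries of each group but do not say that they came from separate cultures. The submitters' processing notes name FastQC 0.11.3, BWA 0.7.17-r1188, ChIPseeker 1.16.1, HOMER 4.9.1 and the genome build GRCm38, without giving the role of each. The name of the deposited list gives PePr as the peak caller, whose version and settings are not given in the sources used here.

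The deposited list has one line per peak for all libraries together. Its fold, a linear ratio of ChSP over input, was computed by the authors, and the scaling between libraries is not given in the sources used here. Its p-value and adjusted p-value per peak were also computed by the authors, and every p was at or below 9.99e-06. The deposited score is a constant multiple of the fold and was not used further. Peak width and the distance to the nearest TSS, with the annotation class and the assigned gene, come from the authors' annotation per the file headers. Widths ran from 200 to 6300 bp in steps of 100 bp, with a median of 600 bp, so peak edges are no finer than that step. The median fold was 21.1 (quartiles 15.5 and 28.6). Peak numbers ran to 9538 with 32 numbers missing, so the list had been filtered after numbering. Fold and p measure different things: across peaks, which are not independent replicates, the Spearman correlation of fold with the size of the negative logarithm of p was 0.753. A p also depends on read coverage and width, which a fold does not show. Read depth is unknown, and intervals given for shares cover counting error only.

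A gene had a promoter peak when a peak assigned to it lay within 1 kb of a TSS. The background was the 21900 protein-coding genes of a RefSeq gene table on GRCm38.p6, and 9503 of the peaks had a gene identifier in that table. Each peak is assigned to 1 gene by the authors' annotation, so a promoter shared by a pair of divergent genes counts for 1 of them. Each of 18 gene lists was tested with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment. The lists covered circadian clock, cAMP signalling, KLF and Sp factors, JAK-STAT signalling, apoptosis, cell cycle, axon growth, synapse and ion channels, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, immediate early genes, SIN3 and HDAC corepressors, thyroid hormone and glucocorticoid action, glial markers, liver and blood markers, chemosensory receptors and histones. The test was tried on simulated lists of 40 genes among 21900 genes, 200 lists per setting. A planted odds ratio of 3 gave a median estimate of 2.82 and passed an unadjusted 0.05 in 89.5% of lists, a planted 6 passed in 100% and a planted 1 in 2.5%. The simulated lists were random, and gene length played no part in the chance of a peak. These rates therefore do not cover lists whose genes differ from others in length. Nor do they cover the adjusted threshold or lists of fewer than 40 genes, the smallest of which had 21.

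The plan was to compare the share of peaks near a TSS with shuffled peaks. The gene table gives no strand, so the shuffles used the share within 1 kb of either end of a protein-coding gene. Motif tests and a background matched on promoter CpG content were also planned and not run, because no genome sequence was used here. Median fold at promoters and beyond 10 kb was compared by a permutation test with 100000 resamples. Alternatives fixed before the data were examined were the peaks with the smallest p, leaving out the 5% widest peaks, a distance of 3 kb, any assigned peak, a background without unnamed gene models, and the mean of log2 fold. Alternatives chosen after seeing the data were leaving out clusters of low-fold peaks, merging peaks closer than 1 kb, peaks at either gene end, a background without receptor genes, and a Cochran-Mantel-Haenszel test within 10 strata of gene length. For the gene lists, the strata were not combined with the background without receptor genes. Counting only named genes without receptors, the shortest stratum held 652 genes and the others 1751 to 2145.

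Named genes followed a rule fixed before the data were examined. It took the 10 genes with the highest promoter fold, the 5 with the highest fold beyond 10 kb, all KLF and Sp genes with a promoter peak together with Klf9 and Klf13, up to 4 members with the highest fold and up to 2 without a promoter peak from each other list past the test, and up to 2 members of each list that did not pass. Unnamed gene models were skipped in the top lists, 0 among promoters and 3 among distant peaks. A gene that the rule takes is not reported here. Klf6, Klf8, Klf12, Klf17, Sp3 and Sp7 were named after their values were seen. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.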

Results

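Chromatin carrying the transcription factor KLF13 was mapped in HT22, an immortalised line of mouse hippocampal neurons. The cells stably made BirA, a bacterial biotin ligase, and were transfected with a plasmid for KLF13 bearing a tag that BirA biotinylates. Chromatin was taken 24 h later and tagged KLF13 was pulled down on streptavidin, a procedure called chromatin streptavidin precipitation (ChSP). There were 4 ChSP libraries and 4 input libraries. No pulldown from cells without tagged KLF13 is among them, so background capture on streptavidin cannot be told apart from KLF13 binding at any peak. One peak list covers all 8 libraries, with a fold of ChSP over input, a p-value and an adjusted p-value per peak, all of them the authors' values. The list holds no value per library, so the spread between replicates and the read depth are unknown, and no fold below carries a replicate error. Coordinates are on GRCm38.

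The first question was where in the genome the ChSP peaks lay. The list held 9506 peaks on 21 chromosomes, assigned to 7800 genes and covering 6.64 Mb. Promoters were taken as within 1 kb of a transcription start site (TSS). The highest promoter fold was at Zfp516 (ENSMUSG00000058881), a zinc finger protein gene, with a fold of 87.6 at chromosome 18, 82914101 to 82915100 (the authors' p = 7.11e-23). Smurf2, a ubiquitin ligase acting on SMAD signalling, had a fold of 84.2 at chromosome 11, 106920001 to 106921200 (the authors' p = 3.18e-32). Zfp217, another zinc finger protein, had a fold of 80.7 at chromosome 2, 170130401 to 170131700 (the authors' p = 7.04e-34). The bicarbonate transporter gene Slc4a7 followed with a fold of 77.9, and Phc1, a Polycomb group gene, with 76.0. Vhl, which encodes the ubiquitin ligase subunit that recognises hypoxia-inducible factors, had a fold of 75.0. Pard6g, a cell polarity gene, had a fold of 73.7, and Bptf, a subunit of the NURF chromatin remodeller, had 73.3. Rcan3, a regulator of calcineurin, and Tdrd7, a Tudor domain gene, had folds of 72.2 and 72.0. All 10 of these peaks overlapped a TSS.

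Promoters held most of the peaks. By the authors' annotation 7599 peaks, or 79.9% (exact 95% binomial interval 79.1 to 80.7), lay within 1 kb of a TSS, and 5984 overlapped one. Distal intergenic peaks numbered 698 (7.34%), intronic peaks 337 (3.55%) and exonic peaks 258 (2.71%). Within 1 kb of either end of a protein-coding gene lay 70.0% of the peaks, against a mean of 4.24% and a maximum of 4.98% over 1000 shuffles of the peaks within their chromosomes (permutation p = 0.001, the smallest these shuffles can give). The promoter share was 90.8% among the 4753 peaks with the smallest p.

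**Figure D1:**
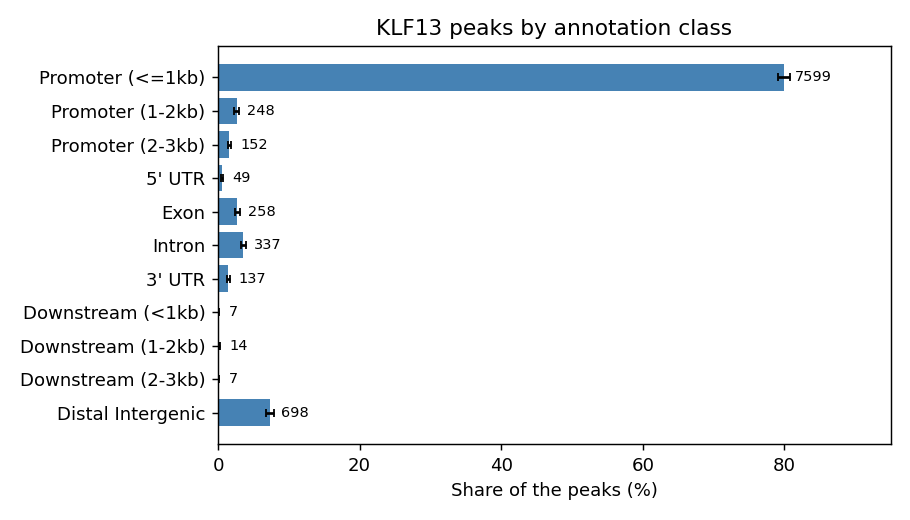
Share of the 9506 peaks in each annotation class, in percent, with exact 95% binomial intervals as error bars and the number of peaks beside each bar. Peaks within 1 kb of a TSS make up 79.9% and distal intergenic peaks 7.34%.

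Folds were higher at promoters than at peaks far from a TSS, which include peaks inside genes. The median fold was 22.2 over the 7599 promoter peaks and 17.2 over the 1017 peaks beyond 10 kb from a TSS. The difference in medians was 5.02 (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest it can give). Among the distant peaks the highest fold, 65.8, was at -61.2 kb from the TSS of Rassf8, a Ras association domain gene, at chromosome 6, 145746201 to 145747200, in intergenic DNA. An intronic peak of Apba1, an adaptor that binds the amyloid precursor protein, had a fold of 55.2. Intergenic peaks near Cfap97, a cilia gene, Fat1, an atypical cadherin gene, and the zinc finger gene Zfp541 had folds of 54.6, 50.1 and 48.9. Peaks are not replicates, so this test describes the list and not the variation between cultures.

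A further question was which genes and pathways had ChSP peaks at their promoters. Of 21900 protein-coding genes, 6769 (30.9%, exact 95% binomial interval 30.3 to 31.5) had a promoter peak. Among 18 gene lists chosen before the data were examined, 10 had a higher share than the remaining genes, 4 a lower share, and 4 did not pass the test (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 18 lists).

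The KLF and Sp family, to which KLF13 belongs, had promoter peaks at 20 of 26 genes (odds ratio 7.47, 95% interval 2.89 to 22.7, exact adjusted p = 8.03e-06). Klf16 and Sp1 had the highest folds, 57.7 and 52.1, followed by Klf4 with 45.2, Sp2 with 45.1, Klf10 with 42.2, Klf3 with 39.6 and Klf11 with 38.8. Klf9, the close paralogue of Klf13, had a fold of 33.0 at chromosome 19, 23141201 to 23142100, over its TSS (the authors' p = 4.67e-19). Klf5, Sp4 and Klf2 had folds of 31.1, 30.9 and 26.6. Sp5, Sp6, Klf15, Sp8, Sp9, Klf14, Klf1 and Klf7 had folds between 22.4 and 10.7. Klf6, Klf8, Klf12, Klf17, Sp3 and Sp7 had no assigned promoter peak, although peaks lay within 1 kb of an end of Klf12, Sp3 and Sp7. The family's odds ratio was 4.38 among the 4753 peaks with the smallest p, 4.56 without the 5% widest peaks and 23.7 with any assigned peak, and it passed in each.

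**Figure D2:**
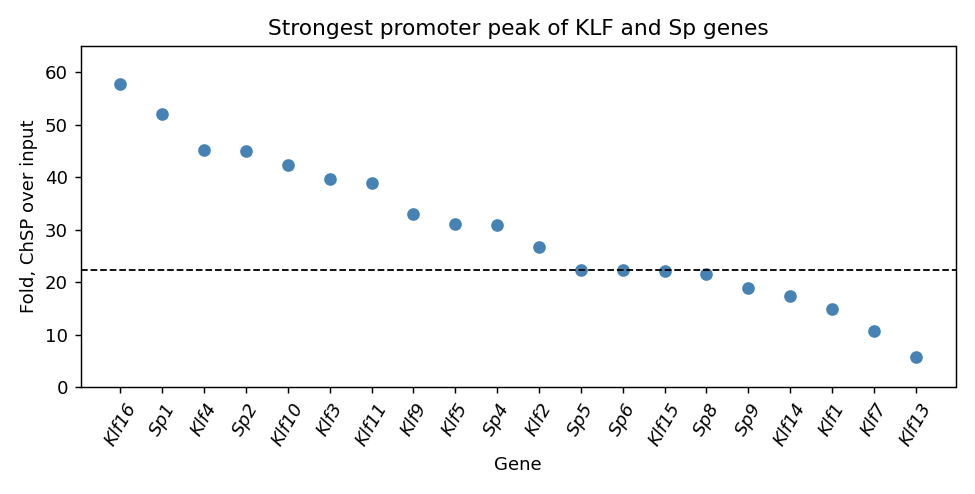
Fold of ChSP over input at the promoter peak with the highest fold, for the 20 KLF and Sp genes that had one, as single values from the deposited list with no replicate error. The dashed line is the median of all promoter peaks, 22.2. Klf16 was highest at 57.7 and Klf13 lowest at 5.70.

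Klf13 itself had the lowest promoter fold of its family, 5.70, with a small p of 6.07e-36, in a peak 2300 bp wide over its TSS at chromosome 7, 63937201 to 63939500. A second peak inside the gene's bounds, at 63891201 to 63892100, had a fold of 4.19 (the authors' p = 1e-11). The authors' annotation gives this peak as 3' UTR and assigns it to the gene model E030018B13Rik, not to Klf13. The transfected plasmid carries Klf13 sequence, so reads at this gene can also come from plasmid DNA. The promoter peak of Klf13 is nevertheless counted in the family's main share and odds ratio above.

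Clock and cAMP signalling genes also had promoter peaks more often than other genes. Of 24 circadian clock genes 18 had one (odds ratio 6.72, 2.55 to 20.7, exact adjusted p = 4e-05). Arntl, which encodes the clock activator BMAL1, had a fold of 45.4, Per3 had 42.9 and the repressor gene Nfil3 had 41.9. Per1 and Nr1d1 had none. With peaks at either gene end the clock odds ratio was 3.01 (1.24 to 7.58, exact adjusted p = 0.0155). Of 38 cAMP signalling genes 28 had a promoter peak (odds ratio 6.28, 2.96 to 14.5, exact adjusted p = 6.37e-07). The folds were 37.4 at Atf1 and 36.8 at Crtc3, a transcription factor and a coactivator of the CREB pathway, 36.1 at the acetyltransferase gene Crebbp, and 35.9 at Prkar1a, a regulatory subunit of protein kinase A. The adenylyl cyclase genes Adcy2 and Adcy4 had no assigned promoter peak, although a peak lay within 1 kb of an end of Adcy4. Within strata of gene length the cAMP odds ratio was 3.50 (1.63 to 7.48, Cochran-Mantel-Haenszel adjusted p = 0.00437, n = 38 genes).

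Genes of the SIN3 and HDAC corepressors had promoter peaks at 16 of 23 members (odds ratio 5.12, 1.99 to 14.7, exact adjusted p = 0.000347). Ing1, a SIN3 complex subunit, had a fold of 52.7, the histone deacetylase genes Hdac4 and Hdac7 had 40.4 and 36.8, and Tbl1xr1, a subunit of the NCoR complex, had 39.2. Sin3b and Hdac3 had none. The odds ratio was 2.63 without the 5% widest peaks (1.06 to 6.58, exact adjusted p = 0.0322) and 3.35 with peaks at either gene end (exact adjusted p = 0.0143). JAK-STAT signalling genes had promoter peaks at 17 of 29 members (odds ratio 3.17, 1.43 to 7.28, exact adjusted p = 0.00349), with folds of 58.0 at the kinase gene Jak2, 52.5 at Pias2, and 52.0 and 46.9 at Socs7 and Socs6, which encode suppressors of cytokine signalling. Jak3 and Tyk2 had no assigned promoter peak, although a peak lay within 1 kb of an end of Jak3. Over the settings run the JAK-STAT odds ratio ranged from 2.58 within strata of gene length (Cochran-Mantel-Haenszel adjusted p = 0.0451, n = 29 genes) to 5.39 among the 4753 peaks with the smallest p (exact adjusted p = 7e-05). Genes of thyroid hormone and glucocorticoid action had them at 13 of 21 (odds ratio 3.64, 1.40 to 10.1, exact adjusted p = 0.00553). Fkbp5, a glucocorticoid receptor co-chaperone, had a fold of 44.0, the coactivator genes Ncoa1 and Ncoa2 had 40.4 and 39.3, and the thyroid hormone receptor gene Thra had 39.3, while Rxrb and Rxrg had no assigned promoter peak, although a peak lay within 1 kb of an end of Rxrb. This last list did not pass without the 5% widest peaks (exact adjusted p = 0.108) or within strata of gene length (Cochran-Mantel-Haenszel adjusted p = 0.128).

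Immediate early genes, which neurons induce on stimulation, had promoter peaks at 15 of 24 members (odds ratio 3.73, 1.53 to 9.68, exact adjusted p = 0.00273). Egr1 had a fold of 33.0, Fosl2 32.5, the phosphatase gene Dusp5 28.6 and the orphan receptor gene Nr4a2 25.2, and Fos and Fosb had no promoter peak. The odds ratio was 6.52 at 3 kb, 9.89 with any assigned peak and 7.40 within strata of gene length. Apoptosis and survival genes had them at 16 of 30 (odds ratio 2.56, 1.17 to 5.66, exact adjusted p = 0.0202). Bcl2, a survival gene, had a fold of 55.6, and the cell death genes Bbc3, Apaf1 and Bcl2l11 had 42.2, 32.4 and 28.8, while Bcl2l1 and Bcl2l2 had no promoter peak. Neither list passed among the 4753 peaks with the smallest p (exact adjusted p = 0.244 and 0.215), and the apoptosis list did not pass with peaks at either end of a gene (exact adjusted p = 0.0608).

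Neuronal genes had promoter peaks more often than other genes, although neither neuronal list passed the test within strata of gene length. Synapse and ion channel genes had them at 24 of 39 members (odds ratio 3.59, 1.80 to 7.36, exact adjusted p = 0.000256). Homer1, a postsynaptic scaffold gene, had a fold of 56.9, the potassium channel gene Kcnq3 had 32.2, the synaptic vesicle gene Vamp2 had 30.3 and the calcium channel gene Cacna1c had 29.4. The sodium channel genes Scn1a and Scn2a had none. Axon growth and guidance genes had them at 23 of 39 (odds ratio 3.22, 1.63 to 6.53, exact adjusted p = 0.000707). The semaphorin receptor gene Plxna1 had a fold of 57.4, Rtn4, which encodes Nogo, had 36.1, the netrin receptor gene Unc5b had 35.0 and the ephrin receptor gene Ephb2 had 34.0. Sema3a and Sema3d had none. Within strata of gene length the odds ratios were 1.55 for the synapse list and 1.40 for the axon list (Cochran-Mantel-Haenszel adjusted p = 0.292 and 0.448, n = 39 genes in each). Among the 4753 peaks with the smallest p the synapse list turned to an odds ratio of 0.794 (exact adjusted p = 0.836), and with peaks at either end of a gene the axon list had an adjusted p of 0.0513.

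**Figure D3:**
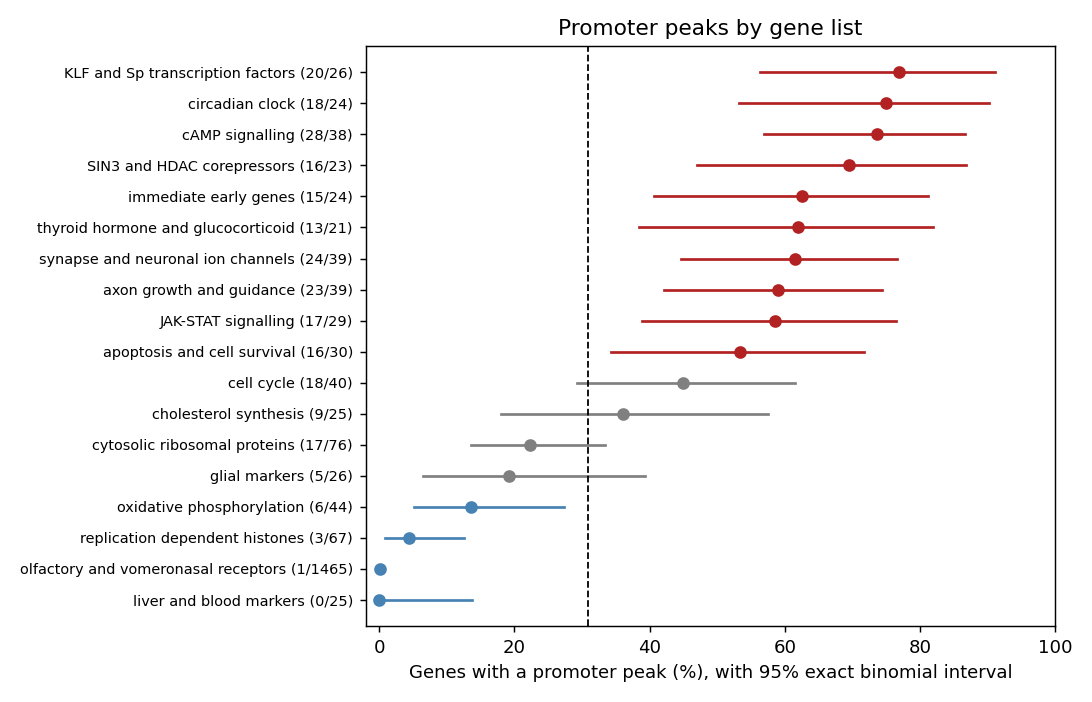
Share of genes with a promoter peak in each of the 18 gene lists, in percent, with exact 95% binomial intervals as lines and the number with a peak over the number of genes in parentheses. Red lists had a higher share and blue lists a lower share past the adjusted test, grey lists did not pass, and the dashed line is the share of all protein-coding genes, 30.9%. KLF and Sp genes were highest, with 20 of 26.

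Fewer promoter peaks than elsewhere were found at 4 lists. Olfactory and vomeronasal receptor genes, which other cell types express, had 1 in 1465 genes (odds ratio 0.00138, exact adjusted p = 1.27e-241), at Olfr94 with a fold of 16.4, and the odds ratio was at most 0.0122 under the settings run. Liver and blood marker genes had 0 of 25 (exact adjusted p = 0.00032), with an exact 95% binomial upper limit of 13.7%. With any assigned peak its odds ratio was 0.0821, and with peaks at either gene end 0.0894. The list of histone genes was taken by symbol prefix to hold replication-dependent ones, and does not hold every histone gene. It had promoter peaks at 3 of 67 (odds ratio 0.104, 0.0210 to 0.319, exact adjusted p = 9.58e-07). The 3 were H2ac21 with a fold of 15.4, H1f0 with 15.1 and H1f10 with 13.6. H1f0 and H1f10 encode linker histones that are made outside S phase as well, so the prefixes also took in genes that are not replication-dependent. Within strata of gene length the histone odds ratio was 1.01 (Cochran-Mantel-Haenszel adjusted p = 0.767, n = 67 genes), among the 4753 peaks with the smallest p 0.0659, and with peaks at either gene end 0.173. Leaving out receptor genes was not combined with these strata, so the value of 1.01 is not shown to come from gene length alone. Oxidative phosphorylation genes had promoter peaks at 6 of 44 (odds ratio 0.352, 0.122 to 0.841, exact adjusted p = 0.0184), with folds of 29.2 at Ndufa4 and at Atp5a1, 22.0 at Ndufv2 and 19.9 at Cyc1, and none at Ndufa1 or Ndufa2. This list did not pass among the 4753 peaks with the smallest p (exact adjusted p = 0.281) or within strata of gene length (Cochran-Mantel-Haenszel adjusted p = 0.172).

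The remaining 4 lists did not differ from other genes past the threshold. Cell cycle genes had promoter peaks at 18 of 40 members (odds ratio 1.83, exact adjusted p = 0.0721), with folds of 45.6 at the kinase inhibitor gene Cdkn1c and 43.4 at the cyclin gene Ccne1. Cholesterol synthesis genes had them at 9 of 25 (odds ratio 1.26, exact adjusted p = 0.665), with 34.3 at Scap and 29.9 at Insig1, which control sterol sensing. Cytosolic ribosomal protein genes had them at 17 of 76 (odds ratio 0.643, exact adjusted p = 0.152), with 30.2 at Rpl14 and 25.0 at Rpl17. Within strata of gene length the ribosomal odds ratio was 1.30 (0.747 to 2.26, Cochran-Mantel-Haenszel adjusted p = 0.493, n = 76 genes). Glial marker genes had them at 5 of 26 (odds ratio 0.532, exact adjusted p = 0.304), with 26.6 at the myelin gene Mbp and 19.3 at the oligodendrocyte regulator gene Sox10.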

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

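No paired analysis was possible because the list holds one value per peak over all 8 libraries, which also rules out leaving out a library in turn. The settings with strata of gene length, either gene end, merged peaks, no receptor genes and no low-fold clusters were chosen after seeing the data. The difference in fold kept its direction and passed under every setting run. Of the 18 lists, all kept direction and side of the threshold at 3 kb, with any assigned peak, without gene models and without the low-fold clusters. With the smallest p, 4753 peaks and 4081 genes were left, and 90.8% of peaks were at promoters. There the odds ratios were 1.87 for apoptosis (Fisher's exact adjusted p = 0.215), 1.80 for immediate early genes (0.244) and 0.559 for oxidative phosphorylation (0.281), while the synapse list turned to 0.794 (0.836). The promoter share was 84.1% within 3 kb of a TSS and 75.8% within 1 kb of either end of any gene. Within strata of gene length the odds ratios were 1.40 for axon genes (0.448), 1.55 for synapse genes (0.292), 0.481 for oxidative phosphorylation (0.172) and 2.36 for thyroid hormone and glucocorticoid action (0.128), and the histone list turned to 1.01 (0.767). With peaks at either gene end they were 2.15 for apoptosis (0.0608) and 2.04 for axon genes (0.0513). Without the widest peaks the thyroid hormone and glucocorticoid list had 2.19 (0.108). The cause of these changes was not tested. The strata were not combined with a background without receptor genes, so shifts there are not shown to come from gene length alone. Over all settings run, adjusted p ranged from 9.22e-06 to 0.0155 for clock genes, 5.91e-08 to 0.00437 for cAMP signalling, 5.8e-09 to 0.00077 for KLF and Sp genes, 7e-05 to 0.0451 for JAK-STAT signalling and 0.000208 to 0.0322 for SIN3 and HDAC genes. It ranged from 0.0202 to 0.215 for apoptosis, 0.000707 to 0.448 for axon genes, 2.13e-05 to 0.836 for synapse genes, 2.79e-06 to 0.244 for immediate early genes, 0.00359 to 0.128 for thyroid hormone and glucocorticoid action, 0.00857 to 0.281 for oxidative phosphorylation, 5.91e-08 to 0.767 for histones and 0.0604 to 0.493 for ribosomal proteins. Motif tests, the CpG-matched background and distances to a recomputed TSS were not run. Unknown depth limits every absence of a peak.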

Other observations

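Families of genes sharing a symbol stem, some of them inside the chosen lists, were scanned after seeing the data. The 111 stems with at least 20 genes, the receptor stems Olfr and Vmn among them, were each compared with the other genes of a background of 18544 named genes without receptors, of which 36.0% had a promoter peak. After Benjamini-Hochberg adjustment over the stems 14 had a higher share and 37, Olfr and Vmn included, a lower one. The scan made no allowance for gene length, with which the share of genes with a promoter peak rose, as given below. Higher shares were found for Map genes, which hold MAP kinases and microtubule-associated proteins, at 35 of 47 (Fisher's exact adjusted p = 1.09e-06), for Ppp genes of protein phosphatases at 49 of 77 (7.21e-06), for Zbtb transcription factors at 29 of 41 (5.29e-05) and for Ube genes of ubiquitin transfer at 29 of 42 (7.58e-05). Lower shares were found for Cyp genes, the cytochrome P450 family, at 5 of 99 (1.31e-11), for Mrpl genes of mitochondrial ribosomal proteins at 3 of 49 (1.05e-05) and for Polr genes of RNA polymerase subunits at 2 of 28 (0.00223). Rpl genes of the large ribosomal subunit, part of a chosen list that did not pass, had 9 of 53 (0.0103), and Rps genes of the small subunit had 13 of 44 (0.559). Within strata of gene length that chosen list had an odds ratio of 1.30, against 0.643 without strata. Zfp zinc finger genes had promoter peaks at 96 of 397 (2.98e-06), also a lower share, although Zfp516 and Zfp217 had 2 of the highest folds in the list, 87.6 and 80.7.

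Outside the clusters of low-fold peaks, Bcor, a corepressor gene on chromosome X, had the most assigned peaks, 13 over 353 kb. The transcription factor genes Pax2, Zfp423 and Casz1 had 7 each. Rnf220, the postsynaptic scaffold gene Shank3, Tbx1, Adgrb1, Bcl11b and the gene model 1700030C10Rik had 6 each. The microRNA gene Mir101c also had 6, none at a promoter, but these lay within 36.6 kb and had low folds of 4.12 to 5.87. The second highest fold in the list, 86.0, was a peak 2139 bp from the TSS of the clock gene Nfil3, at chromosome 13, 52978201 to 52978900. These genes were chosen after their values were seen.

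The share of genes with a promoter peak rose with gene length, from 5.98% in the shortest of 10 strata (median 0.998 kb) to 57.8% in the longest (median 186 kb), among named genes without receptors. No explanation of this was tested. A cluster of 12 peaks, 11 of them with a fold under 8, lay on chromosome 11 from 3101101 to 3289600.

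Of the tests of explanations, those on the chromosome X cluster, on Klf13 and on receptor families were chosen after the results were seen. The tests of DNA dose and of gene length on chromosome X, and those on oxidative phosphorylation genes, were set before their results were seen. Which patterns to weigh was decided after values were seen.

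The larger of 2 clusters of low-fold peaks lay on chromosome X from 162622301 to 164081300. It held 63 peaks, 58 of them with a fold under 8, which is 24.3% of all 239 such peaks, and 4 of the 5 smallest p in the list, at Rbbp7 (1.79e-82), Reps2, Zrsr2 and Syap1. Gene density alone would give the cluster about as many peaks per gene as other windows. It had 5.73, and no other window of its width with at least 5 genes on chromosome X had over 3.0, which argues against gene density. The cluster was picked for its run of low-fold peaks, which favours a high value, so this is not an independent test. Raised local read coverage, such as extra copies of the region, is left open. The cluster's 6 peaks of at least 900 bp had -log10 p at a median percentile of 100 (the smallest p) among 50 peaks matched on fold and width. That median was fixed in advance, because 4 of these 6 peaks hold 4 of the 5 smallest p in the list. For the 57 narrower peaks the percentile was 50, and the list's p threshold keeps the question open there too. That split followed a test of all 63 peaks, which gave 56, and a regression on fold and width, which gave a median residual of 1.87 SD and was set aside because the threshold removes low-fold peaks with larger p.

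Chromosome X as a whole had few promoter peaks, at 127 of 966 genes (13.1%) against 32.1% on autosomes (odds ratio 0.320, 0.262 to 0.387). Without receptor families and gene models the odds ratio was 0.314 (0.257 to 0.382), and within strata of gene length 0.313 (0.255 to 0.383), so neither accounts for it. A lower DNA dose of chromosome X may contribute: its 132 promoter peaks outside the cluster had -log10 p at a median percentile of 14 (95% bootstrap interval 10 to 24), that is larger p, among autosomal peaks matched on fold and width, where 50 was the value without a difference. Copy number was not measured, and no biological explanation was tested.

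The 2 peaks inside the bounds of Klf13, 1 of them assigned to E030018B13Rik, combined a low fold with a small p. Plasmid DNA carrying Klf13 sequence is a possible explanation, and would raise both ChSP and input reads. Among 50 peaks matched on fold and width, -log10 p at the promoter peak lay at percentile 96 and at the other peak at 66, where 100 is the smallest p, so plasmid DNA and binding at the gene cannot be told apart.

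For the lower share at oxidative phosphorylation genes, the odds ratio was 0.481 (0.205 to 1.13) within strata of gene length, which leaves gene length open. With peaks counted at either gene end it was 0.406 (0.153 to 0.923), so the lower share remained when a peak could count for several genes. That measure also uses gene bounds in place of annotated TSSs and loses a gene of the list with a peak over a TSS. It therefore cannot isolate the assignment of 1 gene per peak.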
